A study of Mus musculus with 29 samples.

How the data were processed

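The deposited table holds raw counts per gene for 29 libraries, as integers, and per the labels each column is 1 liver library. The submitters' processing notes name STAR, HTSeq, TopHat, DESeq2, edgeR and STAR-Fusion and the mm10 build. The release of the gene annotation is not given in the sources used here, nor is the strand setting of the counting, so genes that overlap on opposite strands and close paralogs are uncertain. Of 54532 gene identifiers, 54409 were matched to a symbol and position in GENCODE M21 (GRCm38), and the 123 unmatched ones held 0.025% of counts. Totals per library ran from 14385218 to 27278251 counts and were higher in batch 1. PCR copies cannot be removed from gene counts, so an interval from counts covers counting error only.

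Genes were kept by filterByExpr in edgeR (minimum count 10, minimum total 15), which left 15603 genes with 99.92% of all counts. Libraries were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group and a batch term was fitted (common biological coefficient of variation 0.191). The contrasts are K556R against WT when fasted, when refed and as the mean of both, refed against fasted within each genotype, and the difference between the genotype effects. A gene is called at a Benjamini-Hochberg adjusted p below 0.05 across all tested genes of a contrast. Log2 fold changes come with the standard error implied by the quasi-likelihood F statistic. CPM values use the TMM-scaled library sizes, and log2 CPM adds a prior count of 2.

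Gene groups were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry, adjusted over 33 lists per contrast. The lists were written from general knowledge of liver biology before the data were examined, as were the contrasts, the alternatives and the rule for which genes are named. By that rule Prox1 is named in each contrast, with up to 10 called genes per direction by size of change (5 for the interaction), the 4 members of each described list with the smallest p, and the 10 genes with the smallest p where fewer than 5 pass. A called gene needs a mean log2 CPM of at least 1, the same sign in each batch and a symbol other than Gm with digits or ending in Rik. Gm5724, Slco1c1, Gldn, Gm28172 and the p53 targets were added after the results were seen. The camera tests within 1 batch at an estimated correlation were added then as well. Results for 5 single genes that the rule or the lists would name are not reported, though the genes stay in the lists. Counts "adjusted over the list alone" apply the Benjamini-Hochberg step to the list's own members.

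The procedure was tested on simulated data with the same dispersions and group sizes. In the fasted genotype contrast it recovered 30% of genes changed by 1.25-fold, 50% at 1.5-fold, 76% at 2-fold and 96% at 4-fold, with 3 false calls among 129. For the mean of both states it recovered 34%, 80%, 98% and 100%, with 5 false calls among 161, and for refeeding in WT 10%, 52%, 78% and 92%, with 10 among 126. A list of 16 genes changed by 1.3-fold was called, and 0 of 20 unchanged lists were called by camera at its preset correlation. The simulated genes varied independently of each other and the lists were random. This check therefore does not tell how often camera at its preset correlation calls an unchanged list whose genes vary together.

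No library was left out. Libraries were compared in 92 pairs within a group to see whether any are the same RNA sequenced again. All differed beyond counting error (chi-square per degree of freedom 10.9 to 164), among them the 14 pairs of the same group and repeat number in both batches (37.5 to 139), whose residual correlations ran from -0.44 to 0.05. Those 14 pairs are therefore not the same RNA, which does not tell whether they come from the same mouse, and they are taken as separate livers as the labels have it. Libraries sharing a repeat number within a batch correlated at -0.39 to 0.21 over 40 pairs (median -0.095), so no pairing was modelled in the main results. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.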

Results

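Poly-A RNA from the livers of obese male mice was sequenced to ask what a fasting-sensitive SUMO switch on Prox1 does to liver gene expression, with cholesterol metabolism as the subject of the study. Prox1 is a homeobox transcription factor of hepatocytes, and SUMO is a small protein that cells attach to lysines of other proteins. The K556R allele, knocked in only in hepatocytes, swaps the acceptor lysine of Prox1 for arginine so that it cannot carry SUMO. Mice received 45% fat and 20% fructose for 18 weeks after Cre induction at 8 weeks of age, and livers were taken fasted or refed at ZT 15 to 17. The 29 libraries comprise 8 fasted wild-type (WT), 7 fasted K556R, 6 refed WT and 8 refed K556R livers, each group spread over 2 batches. They hold 14385218 to 27278251 gene counts each, and 15603 genes had enough counts to test. Batch accounted for 97.2% of the first principal component, which itself held 37.9% of the variance, so every contrast adjusts for batch and values within each batch are given beside the pooled ones for gene groups called in a genotype comparison. Feeding accounted for 81.1% of the third component, and genotype for 33% of the fourth. Nothing beyond the labels states that replicates are separate animals, so p-values measure the spread between these libraries.

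Whole-gene Prox1 counts did not separate the genotypes in either feeding state. Prox1 (ENSMUSG00000010175, mm10 chromosome 1, 190118035 to 190170714) stood at 174 CPM (counts scaled to the library total, SD 13.0, n = 8) in fasted WT livers and 186 (SD 12.3, n = 7) in fasted K556R livers. Refed livers had 164 CPM (SD 22.7, n = 6) in WT and 150 (SD 25.5, n = 8) in K556R. The K556R versus WT difference was log2 0.092 (SE 0.087, adjusted p = 0.807, edgeR quasi-likelihood with Benjamini-Hochberg) when fasted and -0.14 (SE 0.091, adjusted p = 0.707) when refed. Counts over the whole gene do not show which allele was transcribed, so they do not tell how much of the Prox1 message is mutant.

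What does loss of the Prox1 SUMO site change in the fasted liver? Fasted K556R livers held more transcript of interferon-induced genes than fasted WT livers (n = 7 and 8). Ifi44 rose by log2 1.504 (SE 0.30), Usp18, whose protein strips the ubiquitin-like ISG15 from its targets, by 1.24 (SE 0.23), and Irf7, a transcription factor of the type I interferon response, by 0.97 (SE 0.18). The apolipoprotein L genes Apol9a (1.43, SE 0.27) and Apol9b (0.99, SE 0.21) rose too, as did Rtp4 (0.85, SE 0.17), Trim30d (0.67, SE 0.14), Irf9 (0.56, SE 0.11) and the lectin gene Mbl2 (0.51, SE 0.099). Lipe, which encodes hormone-sensitive lipase, fell by 0.44 (SE 0.088), the asparaginase gene Aspg by 0.40 (SE 0.069) and the mitochondrial chaperone gene Clpb by 0.31 (SE 0.066). Adjusted p lay between 0.0132 for Gldn and 0.0482 for Apol9b and Clpb in this set apart from Gm5724, at 0.000201 (edgeR quasi-likelihood, Benjamini-Hochberg). In mm10, Ifi44 (ENSMUSG00000028037) lies on chromosome 3 at 151730922 to 151749960, Usp18 (ENSMUSG00000030107) on chromosome 6 at 121245906 to 121270917, Irf7 (ENSMUSG00000025498) on chromosome 7 at 141262706 to 141266481 and Lipe (ENSMUSG00000003123) on chromosome 7 at 25379527 to 25398710.

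In all, 16 genes passed in the fasted state, 13 higher and 3 lower, and each had the same sign in both batches. Genes were called on both batches pooled, so such agreement in sign is partly built in, here and in the contrasts below. The set depends on the libraries used: leaving out 1 library at a time gave 2 to 46 genes, and only Gm5724 and Gldn passed in all 29 of these fits. Batch 1 alone gave 31 genes and batch 2 alone 0 by edgeR (982 at an unadjusted p below 0.05), while DESeq2 on both batches gave 89. Effects were larger in batch 1: Ifi44 stood at 2.16 against 0.66 in batch 2, Usp18 at 1.75 against 0.53 and Mbl2 at 0.83 against 0.16, whereas Lipe stood at -0.44 and -0.42. Gm5724 (ENSMUSG00000084927), a member of the organic anion transporter family, had 1 to 29 counts in each of the 15 K556R libraries of either state, and 2 counts in a single WT library of 14. Summed over libraries, 152 counts (129 of them in batch 1) against 2 give a ratio of 72.5 (95% interval 19.7 to 604, counting error only). Its neighbour Slco1c1 was also called (2.67, adjusted p = 0.0482, edgeR), with a median of 11.5 counts in K556R and 1 in WT libraries of batch 1, but of 2 in both genotypes in batch 2. These genes have close relatives in the same cluster, so some of their reads cannot be assigned with certainty.

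The interferon-response genes moved as a group in fasted livers, and the groups for fat and sugar metabolism shifted the other way by small amounts. All 16 interferon genes were higher in K556R, with a median of log2 0.79 (1.247 in batch 1, 0.304 in batch 2, camera adjusted p = 1.01e-33). Adjusted over the list alone, 16 of 16 passed in edgeR, though over all tested genes only 13 genes of any kind were called higher. Of the 17 glycolysis and fructose genes 1 was higher (median -0.17, -0.25 in batch 1, -0.18 in batch 2, adjusted p = 2.94e-05, but adjusted p = 0.32 with an estimated correlation), with Khk, the fructokinase gene, at -0.30 (SE 0.090, not called). The lipid droplet and lipolysis genes had 1 of 19 higher (median -0.15, -0.097 in batch 1, -0.23 in batch 2, adjusted p = 0.00186, but adjusted p = 0.72 with an estimated correlation). Gluconeogenesis genes had 2 of 16 higher (median -0.17, -0.098 in batch 1, -0.22 in batch 2, adjusted p = 0.0102, but adjusted p = 0.767 with an estimated correlation). Cholesterol biosynthesis genes were higher in 17 of 22 (median 0.20, 0.29 in batch 1, 0.007 in batch 2, adjusted p = 0.0174, but adjusted p = 0.785 with an estimated correlation), with Idi1 at 0.67 and Hsd17b7 at 0.37, neither of them called. Fatty acid synthesis genes had 3 of 17 higher (median -0.14, -0.094 in batch 1, -0.28 in batch 2, adjusted p = 0.0447, but adjusted p = 0.785 with an estimated correlation). Pericentral genes had 12 of 15 higher (median 0.096, 0.12 in batch 1, 0.056 in batch 2, adjusted p = 0.049, but adjusted p = 0.767 with an estimated correlation). The camera test uses a preset correlation of 0.01 between genes, and of all groups in the fasted comparison the interferon group alone passed when that correlation was estimated from the data (adjusted p = 0.0254). Of the 8 groups called at the preset correlation, 4 were also called at that correlation in each batch alone: interferon, glycolysis, gluconeogenesis and lipid droplet genes. With an estimated correlation interferon alone passed in batch 1 (adjusted p = 0.0282) and none of the 4 in batch 2 (adjusted p = 0.345 to 0.487). In batch 2 alone the lymphocyte markers rose beside the interferon genes (median 0.57, camera adjusted p = 0.000102, but adjusted p = 0.345 with an estimated correlation), though not in batch 1 (-0.37). The batch 1 value includes replicate 3 of fasted WT, at a mean log2 CPM of 1.578 for these markers. The other fasted WT livers of batch 1 stood at -0.619 to 0.016 and the fasted K556R livers at -0.551 to 0.13. The batches are therefore not shown to differ in direction. The neutrophil markers stood at 1.01 in batch 2 (camera adjusted p = 0.0607, and 0.482 with an estimated correlation).

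Bile acid synthesis genes did not pass as a group in fasted livers (15 genes, median -0.034, camera adjusted p = 0.961). Nor did bile acid transport (19 genes, -0.004, adjusted p = 0.85), sterol uptake (15 genes, -0.026, adjusted p = 0.301) or lipoprotein genes (21 genes, -0.003, adjusted p = 0.301). Cyp7a1, which encodes the first enzyme of bile acid synthesis, stood at 0.38 (SE 0.20, adjusted p = 0.565, edgeR), and Nr0b2, which encodes the bile acid-responsive repressor SHP, at -0.89 (SE 0.26, adjusted p = 0.214). The 18 genes of the SUMO machinery had a median of 0.028 (adjusted p = 0.402). The 4 adipocyte markers were all lower in K556R livers (median -0.36, -0.32 in batch 1, -0.45 in batch 2, camera adjusted p = 0.0447, but adjusted p = 0.263 with an estimated correlation). The batch 2 value includes replicate 2 of fasted K556R, which lay apart at a mean log2 CPM of 5.51 against a median of 6.3 in the others of its group. Lipe is itself expressed in fat, so fat tissue in the samples cannot be set aside for it.

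Does the same allele change the refed liver? No gene passed in the refed comparison by edgeR (1319 at an unadjusted p below 0.05, against 780 that chance gives on average), and DESeq2 gave 44 (n = 6 WT, 8 K556R). Genes that vary together can move such unadjusted counts well away from that average, so 1319 is not read as an excess. All 16 genes called in fasted livers had the same sign here. Usp18 stood at 1.07 (SE 0.25, 1.35 in batch 1, 0.77 in batch 2, adjusted p = 0.122), Xaf1 at 0.88 (SE 0.19, adjusted p = 0.116), Trim30d at 0.75 (SE 0.15, adjusted p = 0.0688) and Lipe at -0.40 (SE 0.094, adjusted p = 0.136). The smallest adjusted p of 0.0688 (edgeR) was shared by Trim30d, Gm5724, Gabarapl1, an autophagy gene, at -0.39 (SE 0.075) and Pcp4l1 at -0.62 (SE 0.12). Without replicate 4 of refed K556R batch 1, 20 genes passed.

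The interferon genes were again higher as a group in refed K556R livers: 16 of 16, with a median of 0.79 (0.99 in batch 1, 0.59 in batch 2, camera adjusted p = 4.16e-31, and 0.0381 with an estimated correlation). Over both states, the mean log2 CPM of these 16 genes in 14 of the 15 K556R libraries lay above that of every WT library of the same batch and state. The group means were 3.41 (SD 0.11, n = 8) in fasted WT, 4.22 (SD 0.63, n = 7) in fasted K556R, 3.48 (SD 0.28, n = 6) in refed WT and 4.21 (SD 0.56, n = 8) in refed K556R.

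**Figure D1:**
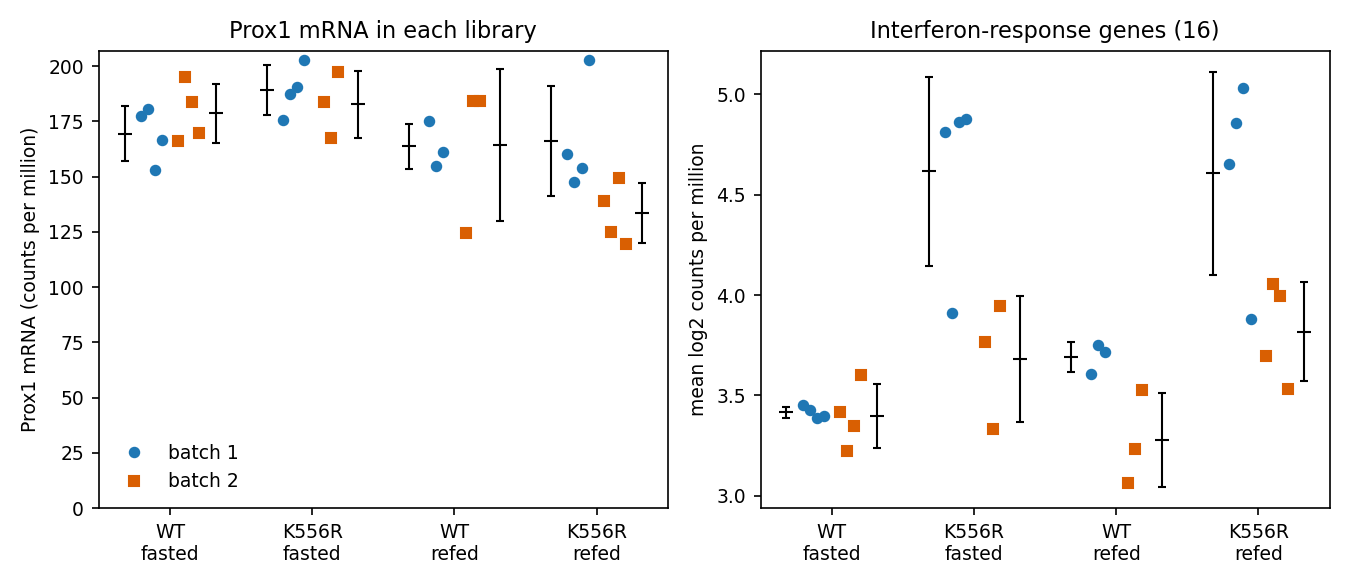
Prox1 in CPM (left) and the mean log2 CPM of 16 interferon-response genes (right) in each library, by genotype, feeding state and batch; bars show the mean ± SD within each batch. Prox1 overlaps between genotypes, while the interferon genes are higher in K556R livers in both states.

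**Figure D2:**
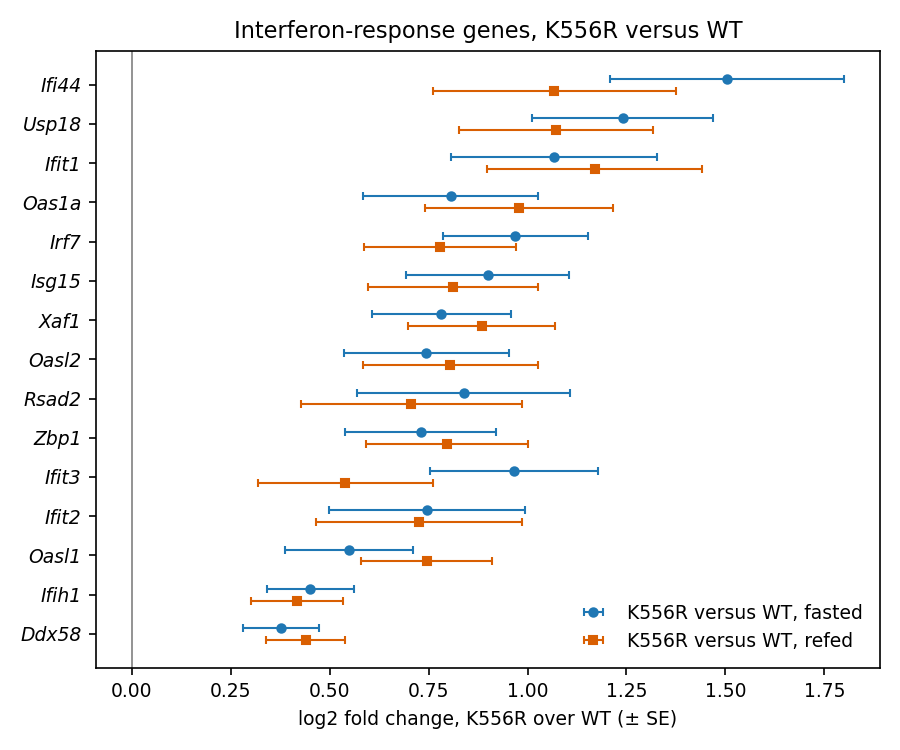
Log2 fold change of K556R over WT (± SE) for 15 of the 16 interferon-response genes, in fasted and in refed livers. All points lie above 0 in both states.

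Refed K556R livers also had more transcript of groups that belong to other cell types or to dividing cells, each of them weak and uneven across batches. Macrophage markers were higher in 17 of 18 genes (median 0.26, -0.013 in batch 1, 0.44 in batch 2, camera adjusted p = 0.00207, but adjusted p = 0.634 with an estimated correlation). Cholangiocyte markers were higher in 9 of 9 (median 0.42, 0.16 in batch 1, 0.70 in batch 2, adjusted p = 0.00463, but adjusted p = 0.425 with an estimated correlation). Stellate and fibrosis markers were higher in 14 of 16 (median 0.24, -0.15 in batch 1, 0.52 in batch 2, adjusted p = 0.0137, but adjusted p = 0.66 with an estimated correlation). The batch 1 value includes replicate 4 of refed K556R, which lay apart at a mean log2 CPM of 2.47 against a median of 3.73 in the others of its group. Proliferation genes were higher in 15 of 16 (median 0.38, -0.12 in batch 1, 0.90 in batch 2, adjusted p = 6.69e-06, but adjusted p = 0.443 with an estimated correlation), with Ccna2 at 0.78 and Mki67 at 0.56, neither of them called. The batch 2 values include replicate 1 of refed WT, whose mean log2 CPM was 1.089 for proliferation (2.057 and 2.133 in the others of its group and batch). For stellate markers it was 2.781 against 3.318 and 3.594. Refed K556R livers of batch 2 stood at 2.298 to 2.949 and at 3.517 to 3.995. Hepatocyte regulators were lower in all but 1 of 18 (median -0.14, -0.081 in batch 1, -0.16 in batch 2, adjusted p = 0.000141, but adjusted p = 0.0839 with an estimated correlation), with Rxra at -0.21 (SE 0.062), not called.

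Metabolic groups in refed livers shifted as follows. Lipid droplet and lipolysis genes had 1 of 19 higher (median -0.17, -0.34 in batch 1, -0.034 in batch 2, camera adjusted p = 0.000157, but adjusted p = 0.425 with an estimated correlation). Replicate 4 of refed K556R batch 1 lay apart here, with a mean log2 CPM of 5.6 against a median of 6.53 in the others of its group. The other refed K556R livers of batch 1 stood at 6.49 to 6.53, against 6.64 to 6.81 in WT. Fatty acid oxidation genes had 3 of 25 higher (median -0.11, -0.25 in batch 1, 0.038 in batch 2, adjusted p = 0.00153, but adjusted p = 0.634 with an estimated correlation). Fatty acid synthesis genes had 12 of 17 higher (median 0.20, 0.009 in batch 1, 0.48 in batch 2, adjusted p = 0.00463, but adjusted p = 0.634 with an estimated correlation), with Fasn at 0.81 (SE 0.32) and the lipase inhibitor gene Angptl8 at 0.97 (SE 0.28), neither of them called. Bile acid synthesis genes had 5 of 15 higher (median -0.12, 0.049 in batch 1, -0.25 in batch 2, adjusted p = 0.0153, but adjusted p = 0.456 with an estimated correlation). Among them Cyp8b1, which sets the share of cholic acid, stood at -0.45 (SE 0.14, adjusted p = 0.353, edgeR) and Cyp27a1 at -0.26 (SE 0.085, adjusted p = 0.381), and adjusted over the list alone 2 genes were lower. Pericentral genes had 3 of 15 higher (median -0.13, -0.10 in batch 1, -0.15 in batch 2, adjusted p = 0.02, but adjusted p = 0.456 with an estimated correlation). Cholesterol biosynthesis had 15 of 22 higher (median 0.14, adjusted p = 0.0221, but adjusted p = 0.791 with an estimated correlation), but its median was -0.37 in batch 1 and 0.51 in batch 2, so the pooled value describes neither batch. The batch 2 values include replicate 1 of refed WT, whose mean log2 CPM was 4.583 for cholesterol biosynthesis (5.369 and 5.797 in the others of its group and batch). For fatty acid synthesis it was 7.921 against 8.616 and 8.811. Refed K556R livers of batch 2 stood at 5.59 to 6.281 and at 8.492 to 9.52. Of the 12 groups called in refed livers, 3 were called in the pooled direction in batch 1 alone and 9 in batch 2 alone, at the preset correlation. The interferon group was the only 1 called so in each, though with an estimated correlation it passed in neither (adjusted p = 0.147 and 0.251), and cholesterol biosynthesis was called lower in batch 1 (adjusted p = 0.0346).

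**Figure D3:**
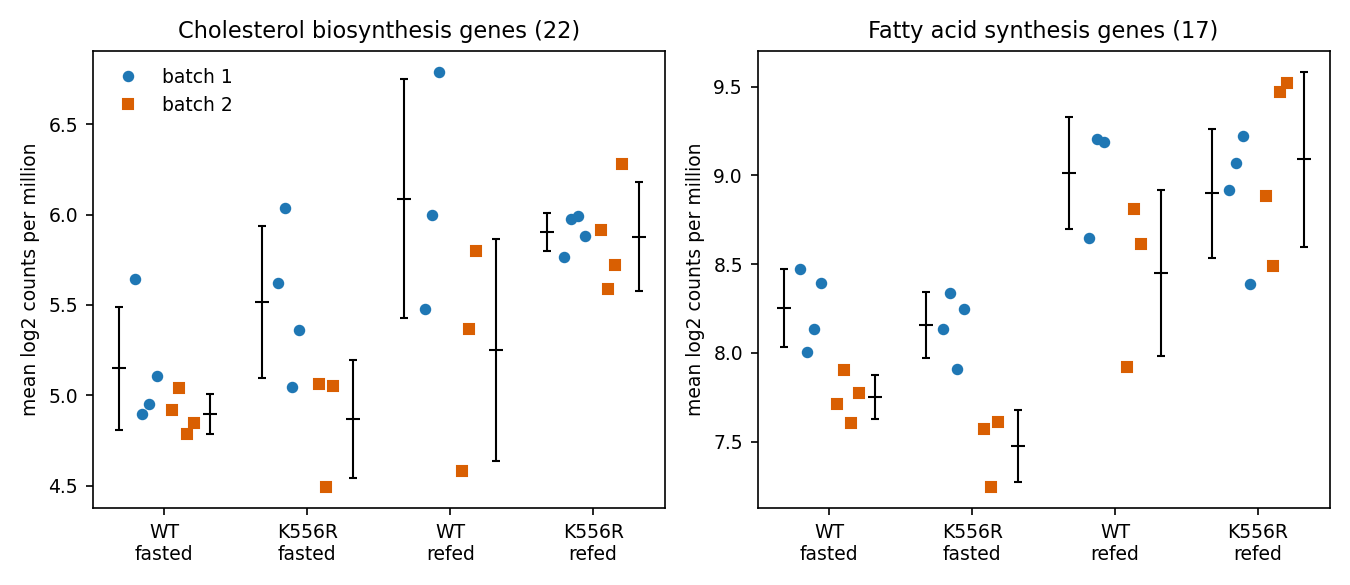
Mean log2 CPM of 22 cholesterol biosynthesis genes and 17 fatty acid synthesis genes in each library, by genotype, feeding state and batch; bars show the mean ± SD within each batch. Both groups are higher after refeeding, and the genotypes overlap.

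Which genes differ between the genotypes when both feeding states are averaged? Taking the mean of the fasted and refed effects (n = 15 K556R, 14 WT), 98 genes were higher and 96 lower in K556R livers. All 194 had the same sign in both batches, an agreement that calling on the pooled batches favours. Interferon genes were among the largest rises of genes with a mean log2 CPM of at least 1, below which several others rose more: Ifi44 rose by log2 1.29 (SE 0.22), Apol9a by 1.24 (SE 0.20), Usp18 by 1.16 (SE 0.17), Ifit1 by 1.12 (SE 0.19), Oas1g by 1.09 (SE 0.21) and Gbp6 by 0.96 (SE 0.17). Gria3, a glutamate receptor subunit gene, rose by 1.07 (SE 0.20), the surface antigen gene Ly6a by 1.04 (SE 0.20) and Eda2r, which encodes a receptor for ectodysplasin A2, by 0.95 (SE 0.20). Lad1, which encodes the anchoring-filament protein ladinin, fell by 0.86 (SE 0.15), the glypican gene Gpc1 by 0.54 (SE 0.091), Lipe by 0.42 (SE 0.064) and Cebpb, which encodes a fasting-responsive transcription factor, by 0.43 (SE 0.097). For these, adjusted p ran from 0.000702 for Usp18 to 0.0222 for Cebpb (edgeR quasi-likelihood, Benjamini-Hochberg), and among the fits without 1 library Cebpb lost its call only without replicate 2 of refed WT batch 1.

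Most of these differences were small: 19 of the 194 exceeded 2-fold, and the median size was log2 0.40. Usp18 stood at 1.55 in batch 1 and 0.65 in batch 2, Lad1 at -0.91 and -0.83, Lipe at -0.45 and -0.38, and Cebpb at -0.48 and -0.38. Batch 1 alone gave 125 genes, batch 2 alone 0 by edgeR (1471 at an unadjusted p below 0.05), DESeq2 426, and leaving out single libraries gave 113 to 299. The largest fall among called genes, of Mup13 (ENSMUSG00000089873, -3.15, SE 0.80, adjusted p = 0.0431, edgeR), rests on 1 library: replicate 1 of refed WT batch 2 held 1620 CPM against a median of 0.276 in the others of its group, and Mup13 has near-identical relatives that share reads. Leaving out single libraries moved Mup13 between -3.35 and -0.36.

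As a group the 16 interferon genes were all called in the mean of both states (median 0.77, 1.12 in batch 1, 0.42 in batch 2, camera adjusted p = 2.61e-45, and 0.00569 with an estimated correlation). Lipid droplet and lipolysis genes were lower in all but 2 of 19 (median -0.16, -0.20 in batch 1, -0.12 in batch 2, adjusted p = 3.04e-05, but adjusted p = 0.264 with an estimated correlation), where Lipe alone was called. The batch 1 value includes replicate 4 of refed K556R, which lay apart at a mean log2 CPM of 5.6 against a median of 6.53 in the others of its group. Hepatocyte regulators were lower in all but 4 of 18 (median -0.09, -0.10 in batch 1, -0.099 in batch 2, adjusted p = 0.00557, but adjusted p = 0.264 with an estimated correlation), with Cebpb called and 4 lower when adjusted over the list alone. Macrophage markers were higher in 18 of 18 (median 0.16, -0.034 in batch 1, 0.33 in batch 2, adjusted p = 0.0156, but adjusted p = 0.646 with an estimated correlation), with Mpeg1 called at 0.41 (SE 0.11) though in only 8 of 29 leave-one-out fits. Proliferation genes were higher in 16 of 16 (median 0.26, 0.13 in batch 1, 0.38 in batch 2, adjusted p = 0.00132, but adjusted p = 0.646 with an estimated correlation). The batch 2 value includes replicate 1 of refed WT, low in these genes as given above. The 4 adipocyte markers were again all lower (median -0.30, -0.37 in batch 1, -0.21 in batch 2, adjusted p = 0.0335, but adjusted p = 0.264 with an estimated correlation). In each batch 1 K556R library lay apart low in these markers: refed batch 1 replicate 4 (mean log2 CPM 4.75 against a median of 6.14 in its group) and fasted batch 2 replicate 2 (5.51 against 6.3). Glycolysis and fructose genes had 3 of 17 higher (median -0.12, -0.19 in batch 1, -0.071 in batch 2, adjusted p = 0.00557, but adjusted p = 0.646 with an estimated correlation). Fatty acid oxidation had 4 of 25 (median -0.098, -0.13 in batch 1, -0.049 in batch 2, adjusted p = 0.00557, but adjusted p = 0.646 with an estimated correlation). Gluconeogenesis had 5 of 16 higher (median -0.12, -0.09 in batch 1, -0.10 in batch 2, adjusted p = 0.0474, but adjusted p = 0.646 with an estimated correlation). Of the 10 groups called, interferon, lipid droplet and hepatocyte regulator genes were called in each batch alone at the preset correlation. With an estimated correlation interferon alone passed in batch 1 (adjusted p = 0.0272) and none of the 3 in batch 2 (adjusted p = 0.359 for each).

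For cholesterol metabolism, the genotype left small and uneven values. Cholesterol biosynthesis genes were higher in 17 of 22 over both states (median 0.18, -0.01 in batch 1, 0.27 in batch 2, camera adjusted p = 0.00557, but adjusted p = 0.646 with an estimated correlation). The batch 2 value includes replicate 1 of refed WT, low in these genes as given above. Adjusted over the list alone no single gene passed in edgeR, with Hsd17b7 at 0.27 (SE 0.11, adjusted p = 0.238) and Mvd at 0.42 (SE 0.24, adjusted p = 0.432). The 21 lipoprotein genes did not pass by camera (median -0.049, adjusted p = 0.106) but did by the fry test for a mixed change (adjusted p = 0.043), and adjusted over the list alone 5 were lower and 1 higher. Apoe stood at -0.20 (SE 0.055, adjusted p = 0.0624) and Apoa5 at -0.22 (SE 0.065, adjusted p = 0.0949). Bile acid synthesis did not pass either (median -0.056, adjusted p = 0.188), with Cyp8b1 at -0.32 (SE 0.098, adjusted p = 0.0955).

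How does the WT liver respond to refeeding? Refed WT livers turned up genes that make fatty acids and cholesterol and turned down genes of fasting, with 819 genes higher and 848 lower than in fasted WT livers (n = 6 and 8). Fasn, the fatty acid synthase gene (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), rose by log2 2.15 (SE 0.32), Pnpla3 by 3.18 (SE 0.58), Srebf1, which encodes the lipogenic factor SREBP-1, by 1.46 (SE 0.15), and Acly by 1.43 (SE 0.26). In cholesterol synthesis and its control, Mvd rose by 2.14 (SE 0.35) and Insig1 by 1.28 (SE 0.21). Pck1, the gluconeogenic gene, fell by 1.53 (SE 0.21), Ppara by 0.67 (SE 0.11), Lipe by 1.04 (SE 0.094), Foxo1 by 0.88 (SE 0.14) and Cebpb by 1.35 (SE 0.15). Angptl4, whose protein inhibits lipoprotein lipase, changed by -1.503 (SE 0.11). Adjusted p ran from 1.97e-10 for Angptl4 to 0.000449 for Acly (edgeR quasi-likelihood, Benjamini-Hochberg).

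Of the 1667 genes called in WT, 1664 had the same sign in both batches and 207 exceeded 2-fold. Batch 1 alone gave 855 and batch 2 alone 596. Leaving out single libraries gave 1302 to 1828 genes. Sult1e1 (2.21, SE 0.72, adjusted p = 0.0451) and Mup13 (3.36, SE 1.03, adjusted p = 0.032) each rest on replicate 1 of refed WT batch 2 and stood at -0.44 and -2.11 without it.

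By groups of genes, refed WT livers had more cholesterol biosynthesis (21 of 22 higher, 12 called, 18 when adjusted over the list alone, median 0.69, 1.01 in batch 1, 0.40 in batch 2, camera adjusted p = 6.36e-09, but adjusted p = 0.438 with an estimated correlation). Fatty acid synthesis was higher as well (16 of 17 higher, 8 called, 9 over the list alone, median 0.45, adjusted p = 3.28e-08, but adjusted p = 0.352 with an estimated correlation). Gluconeogenesis genes were lower (8 of 16 called lower, 10 over the list alone, median -0.42, adjusted p = 3.51e-08, but adjusted p = 0.137 with an estimated correlation). Fatty acid oxidation genes were lower too (7 of 25 called lower, 8 over the list alone, median -0.22, adjusted p = 2.44e-06, with -0.31 in batch 2 but -0.078 and adjusted p = 0.12 in batch 1, but adjusted p = 0.438 with an estimated correlation). Lipid droplet and lipolysis genes (7 of 19 called lower, median -0.18, -0.21 in batch 1, -0.36 in batch 2, adjusted p = 2.44e-06, but adjusted p = 0.276 with an estimated correlation) were lower too. So were glucocorticoid-responsive genes (9 of 10 called lower, median -1.40, -2.18 in batch 1, -0.59 in batch 2, adjusted p = 1.28e-08, but adjusted p = 0.137 with an estimated correlation). Of the 17 acute phase genes 3 were called lower (median -0.34, adjusted p = 0.0028, but adjusted p = 0.438 with an estimated correlation). All 7 groups passed the fry test, which keeps the correlation between genes. That test asks whether the genes of a group changed, not whether they changed more than other genes, which camera asks. Its mixed form called 19 of the 33 lists here. Bile acid synthesis genes did not pass as a group (median -0.069, camera adjusted p = 0.939), with none called by edgeR and Cyp7a1 at 0.55 (SE 0.21, adjusted p = 0.0961).

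Does the K556R liver respond to refeeding in the same way? Refed K556R livers had 1088 genes higher and 1309 lower than fasted K556R livers (n = 8 and 7), and 1257 genes were called in both genotypes, all in the same direction (574 higher, 683 lower, against 57.1 and 71.1 for independent sets). Fasn rose by log2 3.08 (SE 0.34), Pnpla3 by 4.32 (SE 0.60), Angptl8 by 3.30 (SE 0.30), Srebf1 by 2.07 (SE 0.15) and Acly by 2.21 (SE 0.27). Mvd rose by 2.14 (SE 0.35) and Insig1 by 1.43 (SE 0.20). Pck1 fell by 1.65 (SE 0.20), Angptl4 by 1.80 (SE 0.10), Ppara by 0.84 (SE 0.11), Lipe by 0.99 (SE 0.090) and Irs2 by 1.46 (SE 0.24). Prox1 fell by 0.31 (SE 0.087, 0.19 in batch 1, 0.47 in batch 2, adjusted p = 0.0119, edgeR) and was called in each of the 29 fits without 1 library, while in WT livers it stood at -0.086 (SE 0.091, adjusted p = 0.634). Adjusted p for the metabolic genes here ran from 8.28e-13 for Angptl4 to 6.43e-05 for Irs2 (edgeR quasi-likelihood, Benjamini-Hochberg).

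Genes of bile acid metabolism moved a little in refed K556R livers: Cyp27a1 fell by 0.43 (SE 0.082, adjusted p = 0.000361, edgeR), Acox2 by 0.29 (SE 0.073, adjusted p = 0.00556) and the sterol exporter gene Abcg8 by 0.55 (SE 0.12, adjusted p = 0.00157). Nr0b2 rose by 0.85 (SE 0.26, adjusted p = 0.0233) and among the fits without 1 library lost its call only without replicate 4 of fasted K556R batch 1. Abcg8 fell by 0.48 (SE 0.13, adjusted p = 0.011) in WT as well. The bile acid synthesis group did not pass by camera (median -0.057, adjusted p = 0.304) but did by the fry test for a mixed change (adjusted p = 0.00618). Of the 2397 genes called in K556R, 2378 had the same sign in both batches and 323 exceeded 2-fold. Batch 1 alone gave 1512 and batch 2 alone 1927, and leaving out single libraries gave 2037 to 2538.

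**Figure D4:**
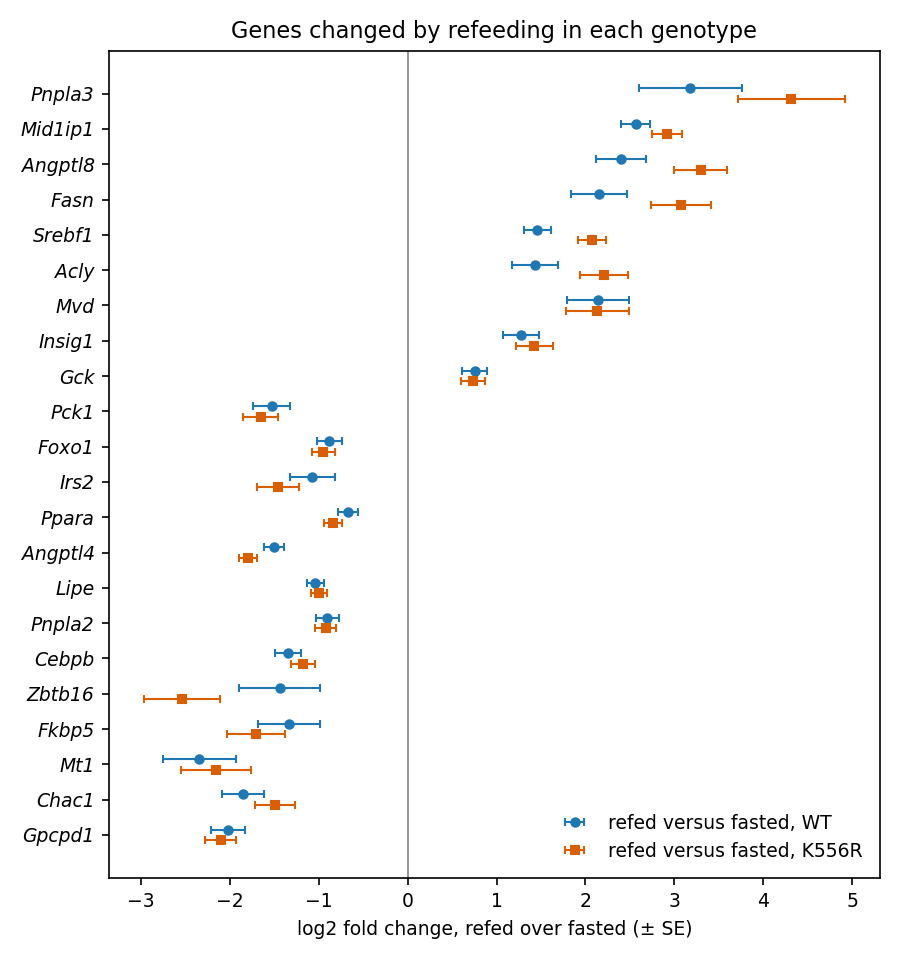
Log2 fold change of refed over fasted livers (± SE) for 22 genes in WT and K556R. Synthesis genes lie right of 0 and fasting genes left of 0 in both genotypes.

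In K556R livers, refeeding raised fatty acid synthesis (17 of 17 higher, 10 called, 11 over the list alone, median 0.60, camera adjusted p = 1.49e-14, but adjusted p = 0.209 with an estimated correlation). It also raised cholesterol biosynthesis (21 of 22 higher, 8 called, 13 over the list alone, median 0.59, 0.27 in batch 1, 1.00 in batch 2, adjusted p = 3.5e-07, but adjusted p = 0.519 with an estimated correlation). Glycolysis and fructose genes were called higher too, but not in batch 1 alone (7 of 17 called higher, 1 lower, median 0.27, 0.41 in batch 2, 0.028 and adjusted p = 0.766 in batch 1, pooled adjusted p = 0.00715, but adjusted p = 0.519 with an estimated correlation). It lowered fatty acid oxidation (10 of 25 called, 15 over the list alone, median -0.25, -0.26 in batch 1, -0.10 in batch 2, adjusted p = 3.06e-07, but adjusted p = 0.343 with an estimated correlation). Gluconeogenesis genes were lower (6 of 16 called lower, 9 over the list alone, median -0.45, -0.86 in batch 1, -0.14 and adjusted p = 0.25 in batch 2, pooled adjusted p = 0.000196, but adjusted p = 0.323 with an estimated correlation). Lipid droplet genes were lower as well (7 of 19 called, median -0.15, -0.39 in batch 1, -0.078 and adjusted p = 0.291 in batch 2, pooled adjusted p = 5.16e-06, but adjusted p = 0.209 with an estimated correlation). Hepatocyte regulators fell in 7 of 18 genes, among them Hnf4a (-0.31, SE 0.063) and Rxra (-0.35, SE 0.060), with a median of -0.20 (-0.12 in batch 1, -0.23 in batch 2, adjusted p = 0.00265, but adjusted p = 0.209 with an estimated correlation). In WT livers Rxra was called lower as well (-0.279 to -0.195 over the leave-one-out fits, called in 27 of 29). Cebpb and Nr1i2 were also called lower in WT, while Foxa3 was called higher. Glucocorticoid-responsive genes (7 of 10 called lower, median -1.52, -2.33 in batch 1, -0.50 and adjusted p = 0.0973 in batch 2, pooled adjusted p = 6.11e-07, but adjusted p = 0.209 with an estimated correlation) were lower as in WT. So were acute phase genes (5 of 17 called lower, median -0.31, -0.30 and adjusted p = 0.0989 in batch 2, pooled adjusted p = 0.00935, but adjusted p = 0.519 with an estimated correlation).

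Does the allele alter the response to refeeding? No gene passed the interaction test by edgeR (440 at an unadjusted p below 0.05, against 780 that chance gives on average, adjusted p = 1 for each gene named here), and DESeq2 also gave 0. Across genes called in either genotype the refeeding effects correlated at r = 0.85, with a slope of 1.07 for K556R on WT among the shared ones. The extra response of K556R stood at 0.92 (SE 0.44) for Fasn, 0.62 (SE 0.21) for Srebf1, -0.61 (SE 0.29) for Cyp7a1, 0.91 (SE 0.38) for Nr0b2 and -0.23 (SE 0.13) for Prox1, so the fall of Prox1 in K556R livers is not shown to differ from WT.

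By groups, fatty acid synthesis genes responded more in K556R livers (16 of 17, median 0.39, 0.019 in batch 1, 0.82 in batch 2, camera adjusted p = 1.75e-06, but adjusted p = 0.617 with an estimated correlation). So did glycolysis and fructose genes (14 of 17, median 0.17, 0.13 and 0.24, adjusted p = 0.00213, but adjusted p = 0.617 with an estimated correlation). Pericentral genes responded lower in 15 of 15 (median -0.20, -0.22 and -0.23, adjusted p = 2.17e-05, but adjusted p = 0.294 with an estimated correlation), with Cyp2e1 at -0.35 (SE 0.19) and Slc1a2 at -0.45 (SE 0.20). Bile acid synthesis genes had 1 of 15 higher (median -0.095, 0.032 in batch 1, adjusted p = 0.0298, but adjusted p = 0.788 with an estimated correlation). Cholesterol biosynthesis did not pass (median -0.09, adjusted p = 0.992), and its batches ran apart, at -0.61 and 0.60. The batch 2 values of fatty acid synthesis and cholesterol biosynthesis include replicate 1 of refed WT, low in both as given above. The fry test called no group here (camera 9, and none with an estimated correlation), and of the 9 only glycolysis and pericentral genes were called in each batch alone at the preset correlation.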

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

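Among the tests in this part, those on leukocyte markers, the exact permutation within each batch, on Cre, on p53 targets as a set, on Gm5724 with the interferon genes and on the neighbourhood of Prox1 were chosen after the result was seen; the others were set before.

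The interferon-response genes were higher in K556R livers of both states, and that the allele itself sets off this response is 1 of the open explanations. More leukocytes in the K556R livers were taken to raise their markers by at least 50% of the interferon median, a threshold set afterwards. In batch 1, 34 leukocyte markers had a median of -0.048 and an upper quartile of 0.087 against an interferon median of 1.12. That argues against a rise of that size. The batch 1 values include fasted WT replicate 3, whose lymphocyte score was 1.578 against -0.619 to 0.016 in the others of its group and batch. Refed K556R replicate 4 was low there, at -0.912 against -0.254 to 0.237, so a smaller rise stays open. In batch 2 more leukocytes are not argued against, since the markers had 0.32 (31 of 34 higher) against 0.42. A difference carried by batch 1 alone is argued against by batch 2, where all 16 genes were higher, though together with the leukocyte markers (fry p = 0.00931, exact permutation p = 0.0114 for the mean of the group over 7 and 7 livers; batch 1 fry 0.000192, exact 0.000816). Cre or its delivery could raise interferon genes in place of the K556R protein, and that stays open because 0 libraries are titled Cre without carrying the K556R allele. An infection or another event in some K556R cages was not tested either.

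Target genes of p53 were also higher in K556R livers, a list prompted by the called gene Eda2r, which it leaves out. The camera and fry p-values for this list are unadjusted, and make no allowance for its having been chosen from these same data. They are therefore not comparable with the adjusted p-values of the planned lists, and do not show that this list would pass among them. Of 28 tested targets 23 were higher (median 0.23, 0.27 in batch 1, 0.17 in batch 2, camera p = 0.0108 with an estimated correlation, fry p = 0.00142), Ccng1, Psrc1, Mdm2 (in 14 of 29 leave-one-out fits) and Plk2 (in 5) were called, and without 3 interferon-linked members camera gave p = 0.0193. Over the 15 K556R libraries the p53 score, without those members, followed the interferon score (r = 0.94, interval 0.825 to 0.98, permutation p = 1e-05, the smallest they can give, Spearman 0.896 with permutation p = 4e-05, r = 0.861 without the 2 farthest libraries), so the 2 responses may be 1 state of the liver. Scores were first centred within group and batch. Neither the interval nor the permutations allowed for that, so both overstate the certainty. No other gene list was compared in this way, so the value does not single out p53 targets. Refed K556R batch 1 replicate 4 and fasted K556R batch 2 replicate 2, low in both scores, were low in female-biased genes too. Their mean log2 CPM there was 0.987 and 1.56, against 3.234 to 3.777 and 2.62 to 2.703 in the others of their group and batch. A wider difference between livers therefore stays open. Over the 14 WT libraries r was 0.427 (interval -0.134 to 0.781, permutation p = 0.13, Spearman 0.455 with permutation p = 0.104, r = 0.097 without the 2 farthest), which leaves open whether this axis exists in all livers; this test was added once the K556R value was known and before the WT value was. Cre without the allele remains a candidate cause here as well, with 0 libraries to test it, and a genuine effect of the allele stays open.

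Gm5724 and Slco1c1, neighbours on chromosome 6, had more reads in K556R livers than in WT, mostly in batch 1. Gm5724 had 129 counts in K556R against 2 in WT there and 23 against 0 in batch 2, while Slco1c1 had medians of 11.5 against 1 in batch 1 and of 2 in both genotypes in batch 2. Reads straying at a steady rate from abundant relatives of the Slco1a and Slco1b families are argued against by the relatives themselves, which had 20509 to 41032 counts per WT library and a summed log2 change of -0.04 (-0.304 to 0.224). A change in the small share of their reads that strays would not show in that sum and was not tested. A change of the whole neighbourhood is argued against by 0 of 7 other tested genes within 500 kb being higher at an unadjusted p below 0.05. The reads might follow the interferon response: over the K556R libraries r was 0.641 (permutation p = 0.0105, Spearman 0.454, permutation p = 0.093), which met the first criterion, but without the 2 farthest libraries r was 0.365, a stricter criterion added after the first value was seen. These permutations too did not allow for the centring within group and batch. A DNA variant carried along with the Cre or the K556R allele was not tested. These reads stay unexplained.

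Genes near Prox1 were tested because flanking DNA can differ around a knocked-in allele. Within 10 Mb of Prox1, 1 of 105 tested genes was called in the mean of both states against 192 of 15487 elsewhere (Fisher's exact p = 1, odds ratio 0.766, 0.0191 to 4.41), which is too wide to exclude flanking DNA. The 1 gene is Gm28172 (-0.76, adjusted p = 0.0378, edgeR), annotated antisense inside Prox1 at 190168670 to 190169633, and it passed in 11 of 29 leave-one-out fits.

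Libraries were shuffled within batch and the other factor into 100 splits each, the real one included. In the fasted comparison 2 of 100 splits gave as many genes as the real 16 (highest other 23). That lies under the share of 0.05 set before, but 100 splits fix so small a share only loosely. Since another split gave more genes than the real one, chance is not excluded for the fasted count. In the refed comparison the real count is 0, so any split gives as many (100 of 100, highest other 10) and the splits test nothing. For the mean of both states only the real split reached 194, 1 of 100 (highest other 0), and refeeding reached 1667 in WT (1 of 100, highest other 2) and 2397 in K556R (1 of 100, highest other 40). For these counts 1 of 100 is the smallest share the splits can give, and it lies under the share set before. That argues against chance only as far as the libraries are separate animals that can be exchanged, which was not tested. For the interaction the real count is also 0 (100 of 100, highest other 0), which tests nothing either.

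A library lay apart from the rest of its group, by Dixon's ratio, in 25 of 324 group tests, where chance flags about 1 in 20 (16). Replicate 4 of refed K556R batch 1 lay apart 6 times: low scores for lipid droplet genes (0.722), adipocyte markers (0.595), stellate markers (0.68) and xenobiotic metabolism (0.766), and low Gria3 (0.531) and Eda2r (0.634). Replicate 1 of refed WT batch 2 lay apart 4 times, with high Mup13 (0.739, 1620 CPM against a median of 0.276), Sult1e1 (0.689, 25 against 0.545) and Apol9a (0.647) and low Cyp26a1 (0.689). Replicate 2 of fasted K556R batch 2 had low adipocyte markers (0.689), proliferation genes (0.598) and Tpm2 (0.695), and replicate 3 of that batch high Cyp26a1 (0.618) and low Cyp2b10 (0.607). Replicate 1 of fasted WT batch 1 had low Trim30d (0.563) and Lipe (0.53), and replicate 3 high Igkc (0.68, 100 CPM against 6.38). Replicate 3 of fasted WT batch 2 had high acute phase genes (0.668) and low Smad9 (0.583) and Upp2 (0.538, 66.2 CPM against 262). The others were Atp2b2, low in fasted WT batch 2 replicate 1 (0.654), Sult1e1, high in fasted WT batch 2 replicate 4 (0.569), Ifi44, high in refed WT batch 2 replicate 3 (0.68), and cholangiocyte markers, high in refed WT batch 1 replicate 2 (0.749).

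The response to refeeding differed between the genotypes for 9 gene groups by camera at its preset correlation, and for none with an estimated correlation or by fry. The adjusted p was 1.75e-06 for fatty acid synthesis, 2.17e-05 for pericentral genes, 0.00213 for glycolysis and fructose use, 0.00288 for proliferation and also for stellate markers, 0.0136 for hepatocyte regulators, 0.0215 for cholangiocyte markers, 0.0298 for bile acid synthesis and 0.0422 for xenobiotic metabolism.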

How the results depend on the processing

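The alternatives below were planned, except for the fit without 2 libraries (replicate 4 of refed K556R batch 1 and replicate 1 of refed WT batch 2) and the tests of genotype by batch at an estimated correlation, which were chosen after the data were seen. On the second principal component they stood at 50.1 and 44.3, while replicate 2 of fasted K556R batch 2 was kept at 43.6. Of the comparisons, genotype in fasted livers gave 16 genes, in refed livers 0 (1319 at an unadjusted p below 0.05) and in the mean of both 194, refeeding gave 1667 in WT and 2397 in K556R, and the interaction 0 (440). RLE scaling gave 18, 0, 197, 1651, 2386 and 0 by edgeR, and the median over all genes stayed near 0. DESeq2 gave 89 fasted (14 shared), 44 refed and 426 in the mean (183 shared). Without the low-count filter 45 fasted (15 shared) and 10 refed genes passed. Without the batch term 2 fasted genes and 98 in the mean passed, all shared. Only the groups compared gave 33 fasted genes (14 shared). With 1 surrogate variable 65 fasted (16 shared), 10 refed and 552 genes in the mean (193 shared) passed. Without those 2 libraries 47 fasted (16 shared) and 3 refed genes passed. The replicate block gave 2 fasted genes and 92 in the mean (90 shared). The interaction was not run with only the groups compared, and gave 0 genes by edgeR under the other settings, each batch alone included, and by DESeq2 (343 to 1650 at an unadjusted p below 0.05). The cause of these shifts was not tested.

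Batch 1 alone gave 31 fasted genes (10 shared), 4 refed, 125 in the mean (88 shared), 855 for refeeding in WT (656 shared) and 1512 in K556R (1107 shared). Batch 2 alone gave 0 fasted genes by edgeR (982 at an unadjusted p below 0.05), 8 refed, 0 in the mean (1471) and 596 for refeeding in WT (497 shared). No difference between batches passed for a single gene when genotype by batch was tested (0 by edgeR, 1358 at an unadjusted p below 0.05), while as a group the interferon genes were less raised in batch 2 (camera adjusted p = 1.06e-16, but adjusted p = 0.363 with an estimated correlation). The same test called 20 of 33 lists at the preset correlation and 0 with an estimated one, where the interferon list had an unadjusted p of 0.011.

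Leave-one-out fits gave 2 to 46 fasted genes, 0 to 20 refed, 113 to 299 in the mean, 1302 to 1828 for refeeding in WT, 2037 to 2538 in K556R and 0 to 0 for the interaction. Fasted counts fell to 2 without fasted K556R batch 1 replicate 1 or 4 or fasted WT batch 1 replicate 2 or 4, to 3 without fasted K556R batch 1 replicate 3 or fasted WT batch 1 replicate 3, and to 5 without fasted WT batch 1 replicate 1 or fasted K556R batch 2 replicate 1 or 3. They were 7 and 10 without refed K556R batch 2 replicates 2 and 3, and 8 without refed WT batch 2 replicate 3. They rose to 45 without fasted K556R batch 1 replicate 2, 36 without fasted K556R batch 2 replicate 2, 30 and 46 without refed K556R batch 1 replicates 3 and 4, and 32 without refed K556R batch 2 replicate 4 or fasted WT batch 2 replicate 4. Refed counts were 20 without refed K556R batch 1 replicate 4, 2 without refed WT batch 2 replicate 2, and 1 each without fasted WT batch 1 replicate 1, refed K556R batch 2 replicate 2 or refed WT batch 2 replicate 1 or 3. The mean was 125 without fasted K556R batch 1 replicate 4, 122 and 299 without refed K556R batch 1 replicates 3 and 4, 127 without fasted WT batch 1 replicate 1, and 113 and 128 without refed WT batch 1 replicates 2 and 3. Among the called genes followed by symbol 2 of 16 fasted, 35 of 45 in the mean, 59 of 79 for refeeding in WT and 80 of 88 in K556R passed in all 29 fits.

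Some values turned. After refeeding in WT, Mup13 was -2.17 without the same 2 libraries and -2.11 without refed WT batch 2 replicate 1 alone, and Sult1e1 was -0.45 and -0.44 (leave-one-out from -2.11 to 4.77 for Mup13 and -0.44 to 2.56 for Sult1e1). In batch 2, refeeding in K556R gave Hsd3b5 -6.91 and Mup7 -7.64 (pooled 3.99 and 3.49, not called). Among lists, cholesterol biosynthesis had a median of 0.007 fasted in batch 2, where camera placed it below the other genes, and -0.37 refed in batch 1. In refed batch 1, bile acid synthesis stood at 0.049, fatty acid synthesis at 0.009, proliferation at -0.12 and stellate markers at -0.15, and in refed batch 2 fatty acid oxidation at 0.038. For the interaction in batch 1, bile acid synthesis stood at 0.032, hepatocyte regulators at 0.035, proliferation at -0.23 and stellate markers at -0.12, and xenobiotic metabolism in batch 2 at 0.074.

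Lists called by camera at the preset correlation numbered 8 fasted, 12 refed, 10 in the mean, 7 for refeeding in WT, 9 in K556R and 9 for the interaction. An estimated correlation gave 1, 1, 1, 0, 0 and 0, directional fry 1, 2, 4, 7, 10 and 0, and mixed fry 0, 0, 3, 19, 21 and 0. Batch 1 alone gave 12 for refeeding in WT, 15 in K556R and 14 for the interaction, and batch 2 alone 14 fasted, 18 in the mean and 16 for the interaction. The sum of libraries of the same group and repeat number across batches was not run, since their residual correlations (-0.44 to 0.05) show that they are not the same RNA.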

Other observations

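The tests in this part were planned, apart from the fit without 2 libraries and the tests within each batch at an estimated correlation, which were chosen after the data were seen, and the results described were picked after their values were seen.

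Refeeding shifted the clock genes in both directions: of 18 circadian clock genes 5 were called higher and 4 lower in WT livers, and 4 higher and 8 lower in K556R livers (fry test for a mixed change, adjusted p = 5.55e-08 and 2.7e-10). Per1, a clock gene that glucocorticoids induce, fell by 1.36 (SE 0.26; adjusted p = 0.000613, edgeR) in WT and by 1.33 (SE 0.24; adjusted p = 0.000202) in K556R. Ciart fell by 1.80 (SE 0.46; adjusted p = 0.00988) in WT. Alongside, the glucocorticoid targets Fkbp5 (-1.34 in WT, -1.71 in K556R), Zbtb16 (-1.44 and -2.54) and Mt1 (-2.34 and -2.16) fell in both genotypes. Refed and fasted livers were taken within the same ZT 15 to 17 window, and where in that window each liver was taken is not known.

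Genes that differ between male and female livers varied widely between livers of 1 group, and in refed livers the genotype differences ran in opposite directions in the 2 batches. The 15 male-biased genes had a median genotype difference in refed livers of 1.47 in batch 1 (camera adjusted p = 6.73e-10, but adjusted p = 0.325 with an estimated correlation) and -1.77 in batch 2 (adjusted p = 2.39e-15, but adjusted p = 0.251 with an estimated correlation), so the opposite medians are not shown to exceed the spread between livers. They pooled to 0.11 (adjusted p = 0.703), and the 11 female-biased genes ran the other way, at -0.50 and 0.51. In fasted livers of batch 2, camera placed the male-biased genes higher in K556R (adjusted p = 0.482 with an estimated correlation), the reverse of the refed livers of that batch. Single livers are a candidate source of part of the refed difference: the mean log2 CPM of the male-biased genes was 8.98 in refed K556R batch 1 replicate 4 against 5.75 to 7.53 in the other livers of that group and batch, and 9.16 in refed WT batch 2 replicate 1 against 6.03 and 6.93. These libraries are 2 of the 3 highest on the second principal component (50.1 and 44.3, with fasted K556R batch 2 replicate 2 at 43.6), and without them Mup13, a male-biased urinary protein gene, went from 3.36 to -2.17 after refeeding in WT. In batch 2 alone, refeeding in K556R gave Hsd3b5 -6.91 and Mup7 -7.64, against pooled values of 3.99 and 3.49 that were not called. There the shift was of a whole group: the mean log2 CPM of the male-biased genes was 5.04 to 5.82 in the refed K556R livers of batch 2. It was 7.67 to 9.12 in the fasted K556R livers of that batch, and 6.03 and 6.93 in its refed WT livers other than replicate 1.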
